A study of Mus musculus with 2 samples.

How the data were processed

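The deposited values were counts of long reads per transcript model, 1 column per library, made by the authors from alignments to mm10 and quantified against GENCODE M21 with models added by TALON, per the files' own text and headers. The deposited counts were whole numbers from 1 up, were not normalized, and were 1 library each, not pooled. The aligner, the versions and the filters were not given in the sources used here. The authors also deposited model lengths and exon numbers, in bases and exons per the file headers, and the start and end coordinates of each model in the deposited annotation files. All 85327 models of replicate 1 and 82087 of replicate 2 were found in the annotation of their library with the same exon number and length. Gene coordinates were taken from GENCODE M21, since 39526 and 39409 of the 55536 annotated genes had the same place in the annotation files.

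The design was taken from the labels, which gave 1 group of 2 replicates, so no contrast between conditions was tested. Results, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Counts of all models of a gene were summed, spike-ins were left out, and CPM was taken on the reads of annotated genes. Genes with at least 10 reads in total were tested between the libraries with a two-sided exact conditional binomial test against the library totals, with Benjamini-Hochberg adjustment, and called at an adjusted p below 0.05 and a fold of at least 2. Log2 ratios used 0.5 reads added to each count, and correlations used 1 CPM. Proportions have Wilson 95% intervals and folds have exact 95% intervals. For a gene with 0 reads in a library the fold is given as a lower bound, the nearer limit of its exact 95% interval. The CPM floors of a count of 0 used 3 reads, its upper 95% limit. No residual degrees of freedom were left for edgeR's quasi-likelihood test, so its exact test with preset variation stood as an alternative.

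The 31 fixed lists covered contraction, calcium handling, ion channels, energy metabolism, transcription and splicing regulators, chambers, cell types, neighbouring tissues, sex, stress, clock and long non-coding RNA genes, and genes alternatively spliced in heart. The reads of each list were tested like those of a gene, adjusted over lists, and its median log2 ratio was placed among 10000 random lists of the same size, matched on expression in 20 bins, with seed 1. Members were also counted after adjustment over the list alone. Paralog shares and isoform use were tested with Fisher's exact test. Genes with more than 1 major isoform had at least 50 reads on annotated models in each library and a second model with at least 20% in both. Isoform use was tested for genes with at least 20 such reads in each library and a leading model below 95%. Unannotated spliced models were matched between libraries by chromosome, strand and intron chain, and unannotated genes by overlap on the same strand.

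Genes were named by a fixed rule. It took the 20 nuclear and 5 mitochondrial genes with the highest mean CPM, the 2 to 4 highest members of each list, both members of each paralog pair and every sex gene. It also took the 10 largest folds each way among called genes, and the 15 most abundant genes with more than 1 major isoform. Genes of the heart splicing list with at least 20 annotated reads in each library, the 10 most used unannotated spliced models, and the 5 highest antisense and 5 highest intergenic genes completed it. Some genes that the rule takes are not reported here. Genes named outside the rule, which include the called genes with overlapping reads, Ppara, the low-count genes of the heart splicing list, the genes called on all models, and the genes of the closing observations, were chosen after their values were seen.

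The design had planned the spike-in measure for SIRV RNAs. The labels named SIRV and ERCC spike-ins, and the ERCC reads were used in their place, as the share of reads on the sense strand. SIRV reads were not analysed here. Alternatives covered scaling (edgeR TMM factors and DESeq2 size factors), read minimums, annotated models only, pseudocounts, the fold minimum, preset variation of 0.1 and 0.2, list composition, isoform minimums and model classes. Removal of the length trend from genes and from lists, lists without their member of lowest p, and a version of isoform use with single-exon models kept apart by class, were added after the data were examined. Single-exon models were pooled per gene in the version on all models after the version by class had been run, since nearly the same stretch of Slc25a4 was classed as an incomplete match in replicate 1 and as genomic in replicate 2. Near-identical copies were genes with a transcript at least 95% identical over at least 80% of its length.

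The tests were tried on simulated libraries. In the same simulation 100 of 9334 genes were changed by 2-fold and 100 others by 4-fold. Of these, 13% (29% without the fold minimum) and 69% were recovered, and 2 unchanged genes were called. The simulated counts held counting error only, which the real libraries exceeded, so the count of false calls does not carry over to them. With the leading share of 200 of 3490 genes moved by 30 percentage points, 61% were recovered and 6 unchanged genes were called. A 2-fold difference in a gene of ordinary abundance was therefore mostly missed at this depth, and genes that did not pass are not shown to be unchanged. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, minimap2 2.31-r1302, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.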

Results

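Long-read RNA sequencing was carried out on heart tissue of 2-month-old female B6CASTF1/J mice, a first-generation hybrid of a C57BL and a CAST inbred strain. The labels gave 1 group, heart, with 2 biological replicates and no treatment, so the comparisons were those between the replicates and those between genes, isoforms and transcript structures within each library. Each library was made from 2 µg of total RNA. The sample labels numbered the animals 3 and 4, whereas the library text named animal 3 for both libraries and both carried the same donor identifier. Whether 2 animals were sampled was therefore not settled by the labels, nor was whether the spread between the replicates is biological. Replicate 1 held 905154 reads on 85327 transcript models and replicate 2 held 745375 reads on 82087 models. Of the reads off the spike-ins, 859191 (96.1%) and 707758 (95.9%) fell on annotated genes, and gene levels are given as reads per 1000000 of these reads (CPM). At this depth 1 read was worth 1.16 CPM in replicate 1 and 1.41 CPM in replicate 2, and a count of 0 allowed up to 3.49 and 4.24 CPM. All intervals, floors and p-values below cover counting error only, since reads without molecular identifiers are not independent molecules. All means are over both replicates and are given ± SD (n = 2).

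The most abundant transcripts were those of contraction, energy supply and oxygen transport. Myh6, the alpha myosin heavy chain of the adult mouse heart, reached 32630 ± 3092 CPM and lay on mm10 at 14:54941921-54966927 on the minus strand. Slc25a4, the ADP/ATP carrier of the inner mitochondrial membrane, followed at 20201 ± 66.9 CPM (8:46206797-46211284, minus strand). Atp2a2, the calcium pump of the sarcoplasmic reticulum, stood at 11181 ± 1572 CPM (5:122453513-122502225, minus strand), and Pln, its inhibitor phospholamban, at 7084 ± 667 CPM (10:53337667-53345987, plus strand). Hba-a1 and Hbb-bs, the alpha and beta globin genes of red blood cells, gave 16698 ± 1371 and 7906 ± 55.2 CPM, and the near-identical alpha globin copy Hba-a2 gave 4563 ± 493 CPM, so that the split of reads between both alpha globin genes is uncertain. Energy metabolism was represented by the ATP synthase subunits Atp5b (10429 ± 147 CPM) and Atp5a1 (6563 ± 360 CPM), the cytochrome c oxidase subunit Cox4i1 (8247 ± 1238 CPM) and muscle creatine kinase Ckm (7356 ± 25.2 CPM). Fatty acid handling was represented by the binding protein Fabp3 (8600 ± 711 CPM), lipoprotein lipase Lpl (6131 ± 97.8 CPM) and the beta-oxidation subunit Hadhb (4659 ± 195 CPM). The remaining genes among the 20 most abundant nuclear ones were Tpm1 (9932 ± 213 CPM), Gsn (7014 ± 440 CPM), Tnnc1 (6576 ± 452 CPM), Myl3 (5147 ± 5.85 CPM), Ndufa4 (5016 ± 524 CPM) and Uqcrc1 (4439 ± 102.2 CPM).

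The 10 most abundant genes took 13.2% of the reads of annotated genes in replicate 1 and 13.4% in replicate 2, and the 100 most abundant took 35.7% and 34.7%. Protein-coding genes held 97.8% and 97.9%. The mitochondrial chromosome contributed 0.620% of reads in replicate 1 (Wilson 95% interval 0.604 to 0.637) and 0.545% in replicate 2 (0.528 to 0.562). The filters used before the deposited counts were not given, so this share need not be that of the tissue. The most abundant genes of this chromosome were mt-Co1 (2013 ± 69.6 CPM), mt-Cytb (1824 ± 417 CPM), mt-Nd2 (420 ± 32.0 CPM), mt-Nd1 (395 ± 2.90 CPM) and mt-Atp6 (246 ± 9.74 CPM). The fixed list of 32 sarcomere and Z-disc genes held 7.49% (7.44 to 7.55) and 7.85% (7.78 to 7.91) of the reads of nuclear genes.

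Paralog pairs of the contractile and metabolic apparatus were compared within each library. Myh6 took 99.7 ± 0.0381% of the reads of Myh6 and its slow paralog Myh7, and the cardiac troponin I gene Tnni3 took 99.8 ± 0.295% against Tnni1. The ventricular regulatory light chain Myl2 took 88.0 ± 3.66% against the atrial Myl7, and the ventricular essential light chain Myl3 took 89.8 ± 1.5005% against Myl4. Cardiac actin Actc1 held 86.3 ± 0.696% against Acta1, and the natriuretic peptide gene Nppa held 97.4 ± 2.03% against Nppb. Among metabolic pairs, Ldhb held 55.0 ± 0.613% against Ldha, Cox6a2 held 95.2 ± 0.556% against Cox6a1 and Cox7a1 held 46.6 ± 2.00% against Cox7a2. The insulin-regulated glucose transporter Slc2a4 held 96.3 ± 1.16% against Slc2a1, muscle-type Cpt1b held 95.2 ± 0.0778% against Cpt1a, and Gata4 held 56.4 ± 6.03% against Gata6. Between the libraries, 3 of the 12 pairs passed a two-sided Fisher's exact test after Benjamini-Hochberg adjustment. Myl2 fell from 90.5% in replicate 1 to 85.4% in replicate 2 (adjusted exact p = 4.73e-07, Fisher's exact test), and Myl3 was 90.8% and 88.7% (adjusted exact p = 3.86e-03). Nppa was 96.0% in replicate 1 and 98.9% in replicate 2 (adjusted exact p = 5.15e-06), and the other 9 pairs had adjusted p of 0.117 or more.

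**Figure D1:**
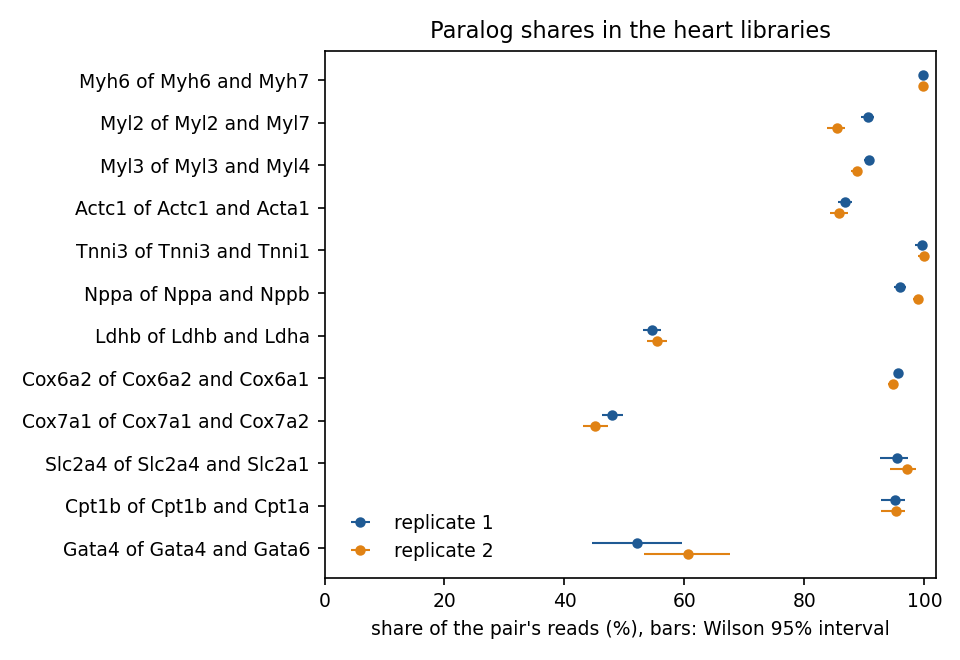
Share of the reads of each of 12 paralog pairs taken by the pair's first-named gene (x axis, %), per replicate, with bars for the Wilson 95% interval. The shares of Myl2 (90.5% and 85.4%), Myl3 (90.8% and 88.7%) and Nppa (96.0% and 98.9%) are the 3 that differed between the replicates beyond counting error.

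Both libraries sampled largely the same annotated genes. A read was found for 14320 genes in replicate 1 and for 14089 in replicate 2, and 12561 of the 15848 genes seen in either library were seen in both. Of those 12561 genes, 11489 were protein-coding, 235 were lincRNA genes and 239 were processed pseudogenes. The 1759 genes seen only in replicate 1 and the 1528 seen only in replicate 2 had a median of 1 read each, a number at which absence from the other library could not be told from chance. Across genes with a read in either library, log2(CPM + 1) values gave a Pearson r of 0.931 and a Spearman rho of 0.925, as a description of the libraries, since genes are not independent replicates. Over the 7260 genes with at least 20 reads in total, the chi-square statistic was 1.81 per degree of freedom, where counting error alone gives 1. The replicates therefore differed by more than counting error and were kept as separate libraries.

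Gene by gene, few differences were large. Of the 9334 genes with at least 10 reads in total, 30 passed an adjusted p below 0.05 and a fold of at least 2 between the libraries in an exact conditional binomial test with Benjamini-Hochberg adjustment, 14 higher and 16 lower in replicate 2. Without the 2-fold minimum 107 genes passed (37 higher and 70 lower in replicate 2), 796 had an unadjusted p below 0.05, and 77.7% of the tested genes lay within 1.5-fold. With 1 group, the test compares the reads of 2 libraries, not conditions. With edgeR's exact test and a preset biological coefficient of variation of 0.1 or 0.2 instead of counting error alone, 12 or 4 genes passed, all among the 30. At 0.2 these were Usp50, Gm10774, Gm45837 and Nt5c1a, and Nppb, Ucp3 and Cfd passed at neither setting.

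Among the genes lower in replicate 2 was Nppb, the gene of B-type natriuretic peptide (4:147985788-147987205, plus strand), with 59 reads in replicate 1 and 16 in replicate 2. Its level was 3.04-fold lower (95% interval 1.73 to 5.66; adjusted exact p = 3.12e-03). Nt5c1a, a cytosolic nucleotidase gene (4:123201504-123216275), had 25 reads in replicate 1 and 0 in replicate 2. It was lower by at least 5.18-fold at the limit of the exact 95% interval, and was not called on annotated models only (log2 ratio -2.88). With the same limit, Fam122a had 21 and 0 reads (at least 4.29-fold lower) and AC129217.1 had 20 and 0 (at least 4.07-fold lower). The lowest p among them was that of the pseudogene Gm10774 (2:126709354-126709557, minus strand), with 290 and 8 reads, 29.9-fold lower in replicate 2 (14.95 to 69.8; adjusted exact p = 8.62e-60). Gm45837 had 56 and 5 reads (9.23-fold lower), Nudc-ps1 had 24 and 3 (6.59-fold, 2.00 to 34.2), Gm28035 had 62 and 8 (6.38-fold), Gm49673 had 29 and 5 (4.78-fold) and Commd9 had 41 and 11 (3.07-fold). Nudc-ps1 and Commd9 lost their call with the length trend removed.

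Higher in replicate 2 was Ucp3, an inner mitochondrial membrane carrier of muscle (7:100472990-100486432, plus strand), with 14 and 38 reads. Its level was 3.30-fold higher (1.75 to 6.58; adjusted exact p = 8.06e-03, exact test). Usp50 (2:126709096-126783470, minus strand) had 3 and 173 reads, 70.0-fold higher (23.6 to 343; adjusted exact p = 1.35e-51). Aldh18a1, a proline synthesis enzyme, had 4 and 25 reads (7.59-fold higher; log2 ratio 1.39 on annotated models only, not called), the inositol trisphosphate kinase gene Itpkc had 7 and 33 (5.72-fold; not called on annotated models only, with a log2 ratio of 0.29, and so uncertain), the pseudogene Gm6969 had 16 and 62 (4.70-fold) and Phyhd1 had 27 and 69 (3.10-fold; log2 ratio 0.59 on annotated models only, not called). Mpped2 had 11 and 31 reads (3.42-fold higher) and Kif16b, a kinesin, had 10 and 28 (3.40-fold). Both lost their call with the length trend removed, and Kif16b also with TMM or DESeq2 factors and on annotated models only (log2 ratio 1.24). At the limit of the exact 95% interval, Mir467f with 0 and 11 reads was at least 3.05-fold higher, and Def6 with 0 and 10 at least 2.72-fold higher. The call of Def6 was lost with the length trend removed and on annotated models only. For 11 of the 30 genes an annotated gene overlapping on the same strand had reads, and with those reads added each came under 2-fold, so these genes are uncertain: Usp50, Gm10774, Gm45837, Pde2a, Gm28035, Phyhd1, Fam122a, AC129217.1, Gm49673, Aldh18a1 and Podn, whose log2 ratio of -1.25 was 0.13 on annotated models only. Gm6969, Nudc-ps1 and Gm49673 came under 2-fold with the reads of near-identical copies added, and are uncertain for that reason. Gm6969 is uncertain also because reads of an unannotated gene beside it on the same strand went the other way (119 and 40).

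**Figure D2:**
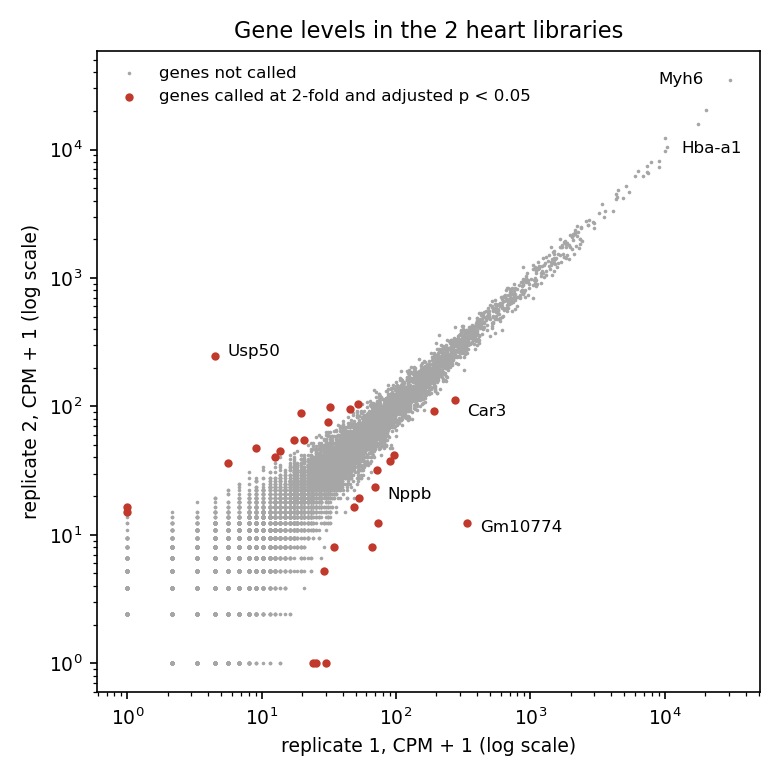
CPM + 1 of each annotated gene in replicate 1 (x axis) and replicate 2 (y axis), both on log scales, with 1 point per gene and the 30 genes called at 2-fold and adjusted p below 0.05 in red. Most genes lie along the diagonal, and Usp50 (3 and 173 reads) and Gm10774 (290 and 8 reads) lie farthest from it among genes with reads in both libraries.

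Contractile and calcium-cycling genes were compared as fixed lists. Each list's reads in replicate 2 over replicate 1 were tested with an exact conditional binomial test adjusted over 31 lists, and 16 passed. The median log2 ratio of 24 lists was placed among matched random lists. It was extreme for the atrial, adipocyte and long non-coding RNA lists only. The others ran from percentile 4.36 (nuclear respiratory chain) to 95.32 (epicardial and mesothelial), with sarcomere and Z-disc at 94.15 and calcium handling at 73.03. Most lists that passed on reads therefore had a median that was not extreme. The sarcomere and Z-disc list was 1.05 times as high in replicate 2 (1.04 to 1.06; adjusted exact p = 2.80e-15). Of its 31 tested members, 4 were higher and 2 lower at an adjusted p below 0.05, none reached 2-fold, and none did when adjusted over the list alone. Myh6 was higher in replicate 2 by 0.19 on the log2 scale (adjusted exact p = 4.76e-48) and troponin C gene Tnnc1 had a log2 ratio of -0.14 (adjusted exact p = 1.82e-04), while Tpm1 (-0.04) and Myl3 (0.00) did not pass. Without Myh6 the list's ratio was 0.982 and did not pass (adjusted exact p = 0.0509), so its call rested on that gene. The calcium handling list stood at 1.03 (1.01 to 1.05; adjusted exact p = 0.0161), but at 0.997 with TMM factors (adjusted exact p = 0.824), which turned its direction, and at 0.897 without Atp2a2 (adjusted exact p = 1.32e-14). Within it Atp2a2 had a log2 ratio of 0.29 (adjusted exact p = 5.18e-36), whereas Pln (-0.19, adjusted exact p = 1.97e-09) and Hrc, a calcium-binding protein of the sarcoplasmic reticulum (2002 ± 410 CPM; -0.42, adjusted exact p = 8.77e-13), were lower in replicate 2. Casq2, which buffers calcium in the same compartment, stood at 1160 ± 22.2 CPM and did not pass. The fall of Pln lay in its single-exon genomic models (4917 and 3310 reads). Its annotated models (1567 and 1366 reads) were not lower relative to the library totals. No member of this list passed at 2-fold, over all genes or adjusted over the list alone. The ion channel and gap junction list stood at 1.10 (1.02 to 1.18; adjusted exact p = 0.0161), no longer passing with TMM factors (1.07, adjusted exact p = 0.136), and none of its 12 tested members passed, over all genes or adjusted over the list alone. Gja1, the main connexin of ventricular muscle, led it with 1202 ± 46.9 CPM, and its other members included Kcnip2 (167 ± 6.09 CPM) and Kcnj11 (152 ± 8.20 CPM).

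Energy metabolism lists differed between the libraries in both directions. The nuclear respiratory chain list was lower in replicate 2, at 0.943 (0.931 to 0.954; adjusted exact p = 7.43e-21), with 8 of 27 tested members lower and 1 higher at an adjusted p below 0.05 and none at 2-fold, nor when adjusted over the list alone. Cox4i1 (log2 ratio -0.31, adjusted exact p = 6.94e-30) and Ndufa4 (-0.21, adjusted exact p = 3.98e-08) were lower and Atp5a1 (0.11, adjusted exact p = 0.0110) higher, while Atp5b (0.03) did not pass. This list's call ended when the trend of the ratio on transcript length was removed (0.988, adjusted exact p = 0.0927). The mitochondrially encoded list was lower at 0.878 (0.842 to 0.915; adjusted exact p = 2.91e-09), with mt-Cytb alone among its 11 tested members passing without the fold minimum (-0.47, adjusted exact p = 1.28e-14) and none called when adjusted over the list alone. Without mt-Cytb the ratio was 0.960 and did not pass (adjusted exact p = 0.236), so the call rested on that gene. Fatty acid oxidation genes did not pass as a list (0.998, 0.982 to 1.01; adjusted exact p = 0.863), and their ratio and their median log2 ratio of 0.06 differed in sign. They passed at 0.969 with TMM factors (adjusted exact p = 4.62e-04) and at 1.03 without Fabp3 (adjusted exact p = 2.05e-03). Their members Fabp3 (-0.17, adjusted exact p = 9.10e-09), Lpl (0.03), Hadhb (0.09) and Acadvl (2213 ± 75.9 CPM; 0.07) stayed below 2-fold, and Ucp3 was the 1 member called, both over all genes and adjusted over the list alone. Glycolysis genes did not pass (1.02, 0.993 to 1.04; adjusted exact p = 0.278; 0.986 with TMM factors), with a median log2 ratio of -0.02, opposite in sign to the ratio. They were led by Aldoa (4355 ± 74.5 CPM), Ldhb (2774 ± 61.4 CPM), Eno3 (2434 ± 64.6 CPM) and Ldha (2268 ± 5.95 CPM), and none of the 18 was called, over all genes or adjusted over the list alone. Gapdh entered this list with 9 and 6 reads, while its near-identical copies, which are not on the list, held 1230 and 1050. The citric acid cycle and energy buffering list stood at 1.02 (1.01 to 1.03; adjusted exact p = 0.0109), and at 0.990 with TMM factors, in the opposite direction and not passing (adjusted exact p = 0.220). Its leading members Slc25a4 (0.01), Ckm (0.01) and Mb, which stores oxygen in muscle (4230 ± 123 CPM; -0.06), did not pass, and no member was called over all genes or adjusted over the list alone.

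Regulators of the heart were detected at lower levels. Esrra, the estrogen-related receptor that controls oxidative metabolism genes, led the 23 cardiac transcription factors at 869 ± 242 CPM and was lower in replicate 2 by a log2 ratio of -0.58 (adjusted exact p = 3.98e-10, exact test), short of 2-fold. Hopx (424 ± 22.4 CPM), Mef2a (165 ± 0.0276 CPM), Gata4 (126 ± 37.9 CPM) and Gata6 (94.8 ± 5.74 CPM) did not pass. The list stood at 0.866 (0.810 to 0.925; adjusted exact p = 5.44e-05) and at 1.01 without Esrra (adjusted exact p = 0.958), and adjusted over the list alone 1 member was called. That member was the fatty acid oxidation regulator Ppara, named after its values were seen, with 24 and 5 reads (-1.88; adjusted exact p = 0.131 over all genes). Splicing regulators stood at 1.13 (1.05 to 1.22; adjusted exact p = 2.04e-03), led by Qk (482 ± 55.9 CPM), Rbm24 (264 ± 9.94 CPM), Hnrnpu (259 ± 31.7 CPM) and Mbnl2 (254 ± 25.8 CPM), with none of 16 called over all genes or adjusted over the list alone. The call ended with the length trend removed (1.07, adjusted exact p = 0.132). Immediate early and stress genes did not pass (1.10, 0.930 to 1.29; adjusted exact p = 0.336) and had a median log2 ratio of -0.11, opposite in sign. Their highest members were Dusp1 (168 ± 46.4 CPM), Ier2 (48.6 ± 1.23 CPM), Dnajb1 (39.2 ± 5.47 CPM) and Junb (36.3 ± 8.57 CPM). Clock genes did not pass (1.15, 0.952 to 1.39; adjusted exact p = 0.232), with Tef (65.7 ± 27.0 CPM), Cry1 (48.3 ± 2.42 CPM), Arntl (37.2 ± 3.28 CPM) and Nr1d1 (34.4 ± 0.712 CPM) highest. Long non-coding RNA genes did not pass (1.07, 0.845 to 1.34; adjusted exact p = 0.647), although the median log2 ratio of their 5 tested members, 0.83, had percentile 99.92 among matched random lists. Mhrt (70.4 ± 5.71 CPM), Neat1 (64.3 ± 11.1 CPM) and Malat1 (37.4 ± 15.04 CPM) led them, and none of these 3 lists had a called member, over all genes or adjusted over the list alone.

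Chamber markers shifted towards atrial genes in replicate 2. The atrial list was 1.25 times as high there (1.18 to 1.31; adjusted exact p = 2.24e-16), and its median log2 ratio of 0.43 had percentile 99.98 among 10000 random lists matched on expression. Nppa, the atrial natriuretic peptide gene (1825 ± 242 CPM; 0.27, adjusted exact p = 1.22e-04), Myl4 (587 ± 96.5 CPM; 0.34, adjusted exact p = 0.0429), Pam (418 ± 97.8 CPM; 0.48, adjusted exact p = 3.62e-03) and Myl7 (368 ± 77.3 CPM; 0.43, adjusted exact p = 0.0372) were each higher in replicate 2 and below 2-fold. The ventricular list was lower, at 0.906 (0.883 to 0.930; adjusted exact p = 2.00e-13), with Pln and Myl2 (2730 ± 376 CPM; -0.28, adjusted exact p = 1.17e-07) lower and Myl3 and Myh7 (90.4 ± 3.90 CPM) not passing. The median log2 ratio of its 5 tested members, -0.19, had percentile 6.52 among matched random lists, which is not extreme. The fall of Pln lay in its single-exon genomic models, not in its annotated ones. Without Pln the ventricular ratio was 0.934 and still passed (adjusted exact p = 7.49e-04). No member of either list was called at 2-fold, over all genes or adjusted over the list alone. Other fixed lists held 5 of the 12 atrial and 5 of the 6 ventricular genes. Conduction system genes (40 reads in replicate 2 and 34 in replicate 1; ratio 1.43, 0.881 to 2.33; adjusted exact p = 0.224) had few reads, with Gjc1 at 30.9 ± 4.23 CPM, Cacna1g at 13.8 ± 6.404 CPM and the pacemaker channel gene Hcn4 at 1 and 2 reads, and 2 of the 9 were also in another list, with none called over all genes or adjusted over the list alone.

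Adipocyte markers had the lowest ratio of the lists with reads in both libraries. They were 0.425 times as high in replicate 2 (0.344 to 0.523; adjusted exact p = 3.81e-17), with 354 reads in replicate 1 and 124 in replicate 2, and their median log2 ratio of -1.20 had percentile 0.02 among matched random lists. Car3, a carbonic anhydrase abundant in fat and skeletal muscle (3:14863512-14872523, plus strand), had 235 and 79 reads, 2.45-fold lower (1.89 to 3.20; adjusted exact p = 2.46e-10, exact test). Cfd, the adipocyte-secreted complement factor D (10:79890853-79892655, plus strand), had 82 and 29 reads, 2.33-fold lower (1.51 to 3.69; adjusted exact p = 6.59e-03). Both were called over all genes and adjusted over the list alone. Cidec (8 and 7 reads) and Ucp1 (9 and 3 reads) did not pass.

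Red cell, stromal and immune markers were also compared. The erythroid list was lower at 0.918 (0.901 to 0.934; adjusted exact p = 9.94e-20), with Hba-a1 (-0.17, adjusted exact p = 1.55e-17) and Hba-a2 (-0.22, adjusted exact p = 6.74e-08) lower and Hbb-bs (0.01) and Hbb-bt (1301 ± 94.8 CPM; -0.15) not passing. With the length trend removed the erythroid list was higher instead, at 1.03 (adjusted exact p = 5.40e-03). Fibroblast markers stood at 0.923 (0.893 to 0.954; adjusted exact p = 5.37e-06), carried by gelsolin Gsn (-0.13, adjusted exact p = 6.77e-04), and at 0.948 without it (adjusted exact p = 0.189). Col3a1 (639 ± 24.1 CPM), Dcn (561 ± 15.4 CPM) and Sparc (331 ± 34.2 CPM) did not pass. Macrophage markers stood at 0.821 (0.708 to 0.951; adjusted exact p = 0.0161), with Lyz2 (195 ± 53.7 CPM), C1qa (58.9 ± 25.3 CPM), C1qb (50.2 ± 3.07 CPM) and C1qc (49.9 ± 1.40 CPM) highest, and did not pass without Lyz2 (0.937, adjusted exact p = 0.684). Lymphocyte markers gave 9 and 20 reads (2.70, 1.17 to 6.73; adjusted exact p = 0.0270), with Ighm at 5 and 8, and on the fewer reads left without Ighm the ratio was 3.64 and did not pass (adjusted exact p = 0.0521). Endothelial markers did not pass (0.964, 0.886 to 1.05; adjusted exact p = 0.438), with Fabp4 at 364 ± 57.6 CPM, Eng at 241 ± 26.6 CPM, Esam at 152 ± 29.7 CPM and Aqp1 at 81.5 ± 6.63 CPM. Pericyte markers (1.07, 0.937 to 1.21; adjusted exact p = 0.396) were led by Rgs5 (378 ± 23.6 CPM), Abcc9 (112 ± 9.85 CPM), Kcnj8 (58.3 ± 3.46 CPM) and Pdgfrb (27.1 ± 3.70 CPM). Smooth muscle markers (0.911, 0.776 to 1.07; adjusted exact p = 0.336) were led by Smtn (230 ± 1.10 CPM), Acta2 (92.4 ± 20.8 CPM), Tagln (33.2 ± 0.934 CPM) and Myh11 (23.0 ± 9.46 CPM). No member of these 7 lists was called at 2-fold, over all genes or adjusted over the list alone, and 1 fibroblast and 1 pericyte gene were in another list.

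Markers of neighbouring tissues were scarce. Epicardial and mesothelial genes gave 61 and 60 reads (1.19, 0.822 to 1.73; adjusted exact p = 0.415), with Upk3b at 31.6 ± 5.23 CPM, Msln at 15.7 ± 5.76 CPM and Aldh1a2 at 11.0 ± 2.41 CPM. Schwann cell genes gave 19 and 23 (1.47, 0.766 to 2.85; adjusted exact p = 0.308), with Cnp at 17.6 ± 5.11 CPM and S100b at 3 reads in each library. Skeletal muscle genes gave 42 and 20 reads (0.578, 0.322 to 1.01; adjusted exact p = 0.0763), nearly all from Tnnt1 (38 and 17), with Tnni2 at 2 reads in each. Lung epithelium genes gave 1 read of Cyp2f2 in replicate 1 and none in replicate 2 (adjusted exact p = 1, exact test), and thymus genes gave 1 read each of Ptcra and Cd4 in replicate 2 and none in replicate 1 (adjusted exact p = 0.301), so no ratio is given for either. The sex list stood at 1.59 (0.726 to 3.55; adjusted exact p = 0.336), with Xist at 4 and 9 reads, Tsix at 9 and 8, and 0 reads for the Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y in both libraries, as far as a floor of 3.49 and 4.24 CPM allows. None of these 6 lists had a called member, over all genes or adjusted over the list alone. Xist was also in the long non-coding RNA list.

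Isoform use was compared within genes on annotated models. Of 1676 genes with at least 50 annotated reads in each library, 168 (10.02%) had a second model with at least 20% of the reads in both libraries, and 1320 gave at least 90% to their first model. The most used model was the same in both libraries for 1655 genes (98.7%). Among the 168 pairs of leading models, 90 had different coding sequences and 59 shared their coding sequence. The other 19 included a model not annotated as protein-coding, which was a retained intron in 10 pairs. A different first exon was found in 48 pairs, a different last exon in 12 and a cassette exon in 43.

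Among the 15 most abundant such genes, 9 had leading models with the same coding sequence. Myh6-201 took 76.2 ± 0.695% and Myh6-205 took 23.0 ± 1.01% of the annotated reads of Myh6, with the same coding sequence of 5814 bases. Annotated models held 51.3% and 50.8% of all Myh6 reads, 18.5% and 20.8% of those of Srl, 35.4% and 33.4% of those of Map7d1 and 33.1% and 35.7% of those of Cd36. Pairs with a shared coding sequence were also leading in Hadhb (56.2 ± 1.13% and 42.0 ± 1.20%), the muscle enolase Eno3 (67.9 ± 0.524% and 28.3 ± 0.716%), Ogdh of the citric acid cycle (78.5 ± 1.36% and 21.04 ± 1.47%) and the complex I subunit Ndufs1 (73.8 ± 0.922% and 25.6 ± 1.20%). The same held for the chaperone Hspa5 (75.7 ± 1.23% and 24.1 ± 1.25%), Atp5g3 (78.0 ± 1.04% and 21.7 ± 1.27%), Myl12a (68.8 ± 4.63% and 30.9 ± 4.22%) and the fatty acid transporter Cd36 (35.7 ± 0.621% and 25.5 ± 2.41%), with a different first exon in Myl12a and Cd36. Proteins differed in Srl (sarcalumenin), where Srl-201 (59.5 ± 2.05%) carried an exon of 1311 bases at 16:4496405-4497715 that Srl-202 (40.5 ± 2.05%) lacked. Srl-201 led among annotated models only, with 200 and 187 reads. An unannotated model with 1227 and 1085 reads, 69.4% and 70.0% of all Srl reads, also skipped this exon, so most Srl reads were on models without it. In Ndrg2 the first model (63.7 ± 3.84%) carried a 42-base exon at 14:51911086-51911127 that the second (36.3 ± 3.76%) lacked. In Gnas, the G protein alpha subunit gene, the second model (34.1 ± 1.65%) held a 45-base exon at 2:174336747-174336791 that the first (41.1 ± 0.823%) lacked. Map7d1 (60.3 ± 5.57% and 25.8 ± 1.39%) and Chpt1 (54.0 ± 1.66% and 35.9 ± 0.502%) also had leading models with different coding sequences. In Cox4i1 the leading model was Cox4i1-204, with 65.6 ± 3.41% against 33.7 ± 3.28% for the coding Cox4i1-201. Cox4i1-204 is annotated as a retained intron with no coding sequence, 578 bases in 3 exons at the 3' part of the gene (8:120672590-120674113). Whether its reads were incomplete reads of coding transcripts was not tested.

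Genes on the fixed list of 38 that are alternatively spliced in heart were read on annotated models at this depth in part. For 15 of them each library held at least 20 annotated reads, and the shares of models below are of these annotated reads. Tropomyosin Tpm1 used Tpm1-205 for 99.2 ± 0.0868%, Actn2 used Actn2-201 for 99.2 ± 0.0425%, Atp2a2 used Atp2a2-202 for 97.6 ± 0.126% and Atp5c1 used Atp5c1-201 for 98.5 ± 0.761%. Pyruvate kinase Pkm gave 95.2 ± 0.341% to Pkm-202, with the exon at 9:59675029-59675195, and 4.80 ± 0.341% to Pkm-201, which has the mutually exclusive exon at 9:59675568-59675734. The phosphate carrier Slc25a3 gave 95.4 ± 0.814% to Slc25a3-206, with a 125-base exon at 10:91122207-91122331 in place of the 122-base exon of Slc25a3-201 (2.81 ± 0.629%). Ldb3 used the short Ldb3-203 for 86.2 ± 0.891%, Asph-206 took 65.9 ± 3.92% of the annotated reads of Asph, Dnm1l-201 took 95.8 ± 1.44% of the 38 and 31 of Dnm1l, and Fxr1-201 took 95.7 ± 6.15% of the 27 and 23 of Fxr1. Mef2a-208, with a 24-base exon at 7:67244521-67244544, took 54.9 ± 1.24% of the 37 and 43 annotated reads of Mef2a. Vegfa-207, with a 72-base exon at 17:46022277-46022348, took 51.1 ± 2.65% of the annotated reads of Vegfa against 43.0 ± 0.775% for Vegfa-202, which lacks it. Trdn, encoding triadin, divided between the single-exon Trdn-204 (46.8 ± 5.37%), annotated as a retained intron, and the coding Trdn-208 (42.8 ± 0.890%), which was the higher of both in replicate 2. Camk2d and Dtna had few annotated reads (44 and 54, and 27 and 23). Camk2d-226 had the highest mean share among the annotated models of Camk2d but took 18.2% in replicate 1, where Camk2d-202 and Camk2d-204 took 29.5% each, and 40.7% in replicate 2. Dtna-206 took 62.6 ± 9.91% of the annotated reads of Dtna. Unannotated combinations of known splice sites held 44.7% and 45.2% of all reads of Camk2d, 46.5% and 46.2% of those of Mef2a and 47.1% and 52.8% of those of Dnm1l, and the most used model of Camk2d (37 and 33 reads) and of Mef2a (38 and 41 reads) was among them. Incomplete matches held 33.3% and 40.6% of the reads of Ldb3, and annotated models held 35.1% and 36.5% of those of Fxr1. Of the 10 list genes with at least 50 annotated reads in each library, Vegfa and Trdn were the 2 with a second model above 20%.

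The other 23 genes of that list had fewer annotated reads, and some of them also had many reads on other structures. Titin (Ttn) had 123 and 108 reads, of which 2 and 0 were on annotated models and 67.5% and 75.9% on incomplete matches of annotated transcripts. Troponin T gene Tnnt2 had 327 and 231 reads, of which 1 and 0 were on annotated models and 78.3% and 83.1% on incomplete matches. The ryanodine receptor gene Ryr2 had 108 and 98 reads and none on annotated models. In Pdlim5 75.4% and 72.3% of reads, and in Ktn1 85.0% and 82.6%, were on unannotated combinations of known splice sites, and in the formin gene Fhod3 43.3% and 53.6% were on models with a splice site outside the annotation. As a list, these 38 genes were 1.08 times as high in replicate 2 (1.06 to 1.10; adjusted exact p = 4.21e-18, exact test) and 1.02 without Atp2a2 (adjusted exact p = 0.185), Atp2a2 alone being higher without the fold minimum and no member being called over all genes or adjusted over the list alone. Another fixed list held 24 of the 38.

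Isoform use differed between the libraries in 1 of 1037 genes tested with Fisher's exact test on annotated models. That gene was Cox4i1, in which Cox4i1-204 took 68.0% of annotated reads in replicate 1 (66.9 to 69.0) and 63.1% in replicate 2 (61.8 to 64.5), a difference (replicate 2 minus replicate 1) of -4.83 percentage points (adjusted exact p = 1.95e-05). Whether incomplete reads of coding transcripts made this difference was not tested. At an unadjusted p below 0.05 there were 42 genes. With all models of a gene counted and single-exon models pooled, 7 of 4082 genes passed: Cox4i1, Slc25a5, Pln, Atp5b, Actn2, Des and Phyhd1. Named after their values were seen, Slc25a5 gave 71.0% and 58.4% of its reads to single-exon models (adjusted exact p = 4.30e-07) and Pln 75.7% and 70.7% (adjusted exact p = 4.92e-06).

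Most reads matched annotated transcripts in structure. Annotated models held 72.8 ± 0.318% of the reads off the spike-ins, incomplete splice matches (ISM), which lack a part of an annotated transcript, held 10.1 ± 0.557%, and models with a new combination of known splice sites (NIC) and with at least 1 new site (NNC) held 4.98 ± 0.371% and 3.24 ± 0.278%. Genomic models, which overlap a gene without following its introns, held 5.06 ± 0.0913%, antisense models 3.27 ± 0.0567% and intergenic models 0.618 ± 0.0778%. Of the ISM reads, 69.8% in replicate 1 and 75.9% in replicate 2 were on models that keep the 3' end of the transcript. Models with 1 read made up 61.2% and 62.7% of all models.

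**Figure D3:**
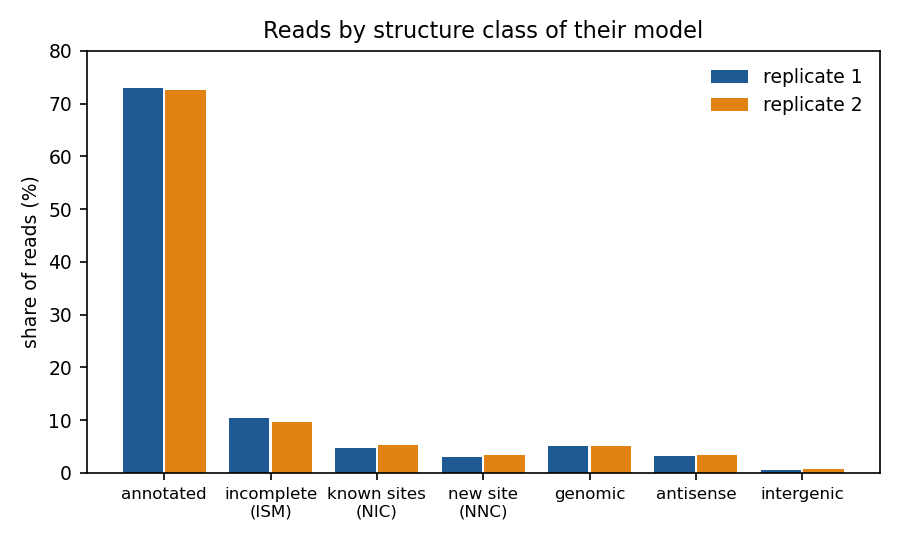
Share of reads off the spike-ins (y axis, %) by structure class of the transcript model, with 1 bar per replicate. Annotated models hold 73.0% and 72.5% of the reads, and each of the other 6 classes holds 10.5% or less.

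Unannotated spliced models recurred where reads were many. Of the 25736 NIC and NNC models of replicate 2, the shallower library, 30.04% (29.5 to 30.6) had the same intron chain as a model of replicate 1, and these carried 69.0% of the NIC and NNC reads of replicate 2. The share was 97.6% among models with at least 5 reads. The most used was a 39-exon Myh6 model (14:54941921-54966574) with 4022 and 3651 reads, 15.4% and 14.8% of the gene's reads, and a second Myh6 model of 39 exons had 1133 and 1168. In Oaz1, an inhibitor of ornithine decarboxylase, an unannotated 5-exon model (10:80826682-80829284) held 96.0% and 96.3% of the gene's reads (1482 and 1266). Srl gave 69.4% and 70.0% of its reads (1227 and 1085) to a 6-exon model reaching to 16:4476979, which lacked the 1311-base exon of Srl-201. All introns of these 4 models and of the Tmed2 model (400 and 366 reads, 83.5% and 82.1%) were in the annotation, in another combination. Known splice sites were joined by an unannotated intron in Idh3b (2:130279438-130280262; 616 and 497 reads, 81.8% and 80.2%) and in Mpc1, a pyruvate carrier subunit (17:8283962-8296534; 383 and 333 reads, 95.04% and 95.4%). A splice site outside the annotation was used in Atp2a2 (intron 5:122500814-122501563; 456 and 492 reads, 5.27% and 5.66%), Vdac3 (8:22583737-22587548; 377 and 326 reads, 89.3% and 87.9%) and Idh3g (X:73782104-73782670; 345 and 319 reads, 90.6% and 91.7%). Mpc1 and its pseudogene Mpc1-ps share near-identical sequence, so the reads of Mpc1 are uncertain.

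Reads outside annotated genes were spread over many low models. Replicate 1 held 10605 unannotated antisense genes and replicate 2 held 10341, and 4323 overlapped on the same strand between the libraries. Among the highest were those opposite Gm26917 at 17:39843013-39845074 (1190 and 756 reads, against 12 and 12 on Gm26917) and opposite the muscle kelch gene Klhl31 at 9:77656667-77657521 (587 and 371). Others lay opposite Tmem250-ps at 2:26136814-26138383 (493 and 353) and Tnnt2 at 1:135849741-135850379 (311 and 225, against 327 and 231 on Tnnt2 itself). Intergenic genes numbered 2685 and 3339, of which 632 overlapped. The highest lay at 11:31545795-31549650 on the plus strand (250 and 219 reads), 7:19933824-19933992 (160 and 64), 15:103619062-103619240 (134 and 70), 12:24638003-24638669 on the minus strand (119 and 40) and 8:77960114-77985239 (81 and 55). In replicate 1 the region on chromosome 12 directly adjoined the called pseudogene Gm6969 on the same strand, and in replicate 2 it was 12:24637993-24638134. Its reads fell (119 and 40) while those of Gm6969 rose (16 and 62), and the check of overlapping genes took in annotated genes only.

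Model lengths over reads were compared between the libraries. The median over reads was 1789 bases in replicate 1 and 1925 in replicate 2, and 1896 and 1925 on annotated models alone. Models under 1000 bases held 29.4% and 25.7% of reads, and 25.8% and 23.0% on annotated models alone. These are lengths of the models, not of the reads, and single-exon models can be very short: a Ryr2 genomic model of 2 bases held 42 reads in replicate 1. They were also drawn differently in each library, the most used model of Pln being 787 bases long in replicate 1 and 2473 in replicate 2. With genes put in 10 equal groups by model length, the shortest group (median 754 bases) had a median log2 ratio of replicate 2 over replicate 1 of -0.16, and the longest group a median of 0.14. Among ERCC spike-ins, synthetic RNAs of 273 to 1994 bases, 48 species had reads in either library and 36 in both. They took 10926 reads (1.21%) in replicate 1 and 7204 (0.966%) in replicate 2, and their log2 counts had a Pearson r of 0.968 between libraries. Of reads on spike-in sequences, 99.2% (99.0 to 99.3) and 99.4% (99.2 to 99.5) were on the annotated sense strand.

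**Figure D4:**
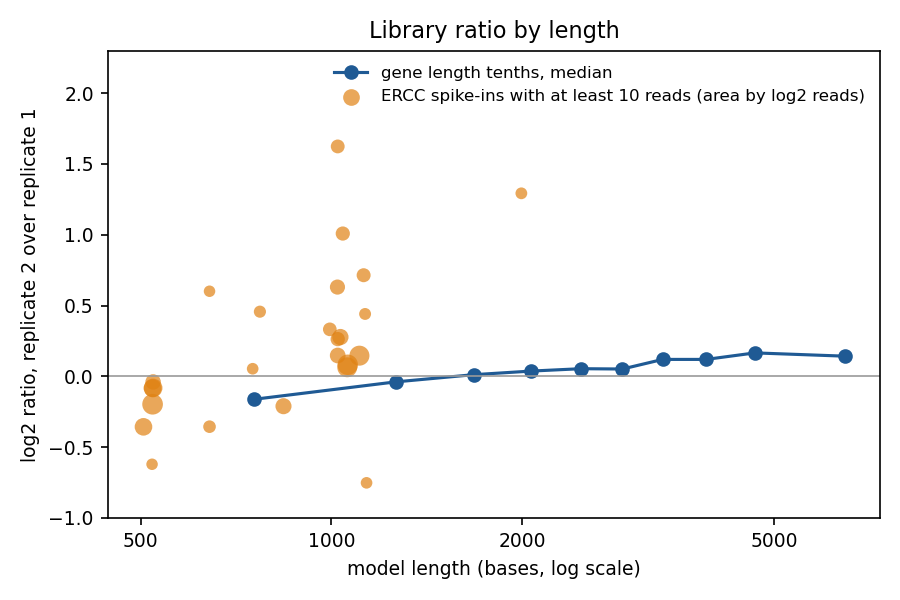
Log2 ratio of replicate 2 over replicate 1 (y axis) against model length in bases (x axis, log scale), with the median of each of 10 groups of genes by length as joined points and ERCC spike-ins with at least 10 reads as circles whose area follows their log2 reads. The gene medians run from -0.16 in the shortest group to 0.14 in the longest, and the spike-ins scatter more widely.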

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

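The removal of the length trend, the version of isoform use by class and lists without their member of lowest p were chosen after the data were examined. Of 115 alternatives to 30 results, 76 left the value the same and 39 moved it, and 48 of the 76 left out 1 replicate. All 50 alternatives to the mean CPM of the 20 nuclear and 5 mitochondrial genes also left out 1 replicate and moved no value. For a mean this follows from the design, since each of 2 replicates lies within 1 SD of their mean, so it is no sign of stability. Shares of single isoforms were not put through it, and Camk2d-226 (18.2% and 40.7% of annotated reads) was the leading annotated model of Camk2d in replicate 2 only. Leaving out a replicate was not possible for tests between the libraries, detection in both, the correlation and shared models. No paired analysis was possible because the labels gave 1 group.

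Of 293 alternatives to the folds of the 30 called genes, 204 left the call the same and 88 ended it with the direction kept. Podn, with a log2 ratio of -1.25, reversed to 0.13 on annotated models only, and the cause was not tested. Genes detected in both libraries numbered 6741 with at least 10 reads, in place of 12561, by construction. The Pearson r of 0.931 was 0.790 with 0.1 CPM added, 0.977 with 10 CPM added and 0.949 over genes with at least 10 reads, and Spearman's rho was 0.925. The 30 called genes became 15 on annotated models only (13 of them among the 30), 107 with no fold minimum, and 12 and 4 with preset variation of 0.1 and 0.2. The cause of the first was not tested, and the others follow from the looser or stricter rule.

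Of 116 alternatives to 29 lists, 81 left the direction and the call the same, 16 ended a call, 1 made one and 18 reversed the direction. Without the member of lowest p, a change that takes the gene of strongest difference from each list, 8 lists passed in place of 16, and 6 of these were among the 16 with the same direction. Without the most abundant member, the ratio was 0.982 for the sarcomere list, 0.897 for calcium handling, 1.03 for fatty acid oxidation, 1.01 for cardiac transcription factors, 1.03 for endothelial markers and 0.864 for immediate early genes, by construction. With TMM factors it was 0.997 for calcium handling, 0.986 for glycolysis and 0.990 for the citric acid cycle list. With the length trend removed it was 0.979 for calcium handling, 0.978 for pericyte markers and 1.03 for the erythroid list, and the cause of these was not tested. Without the member of lowest p it was as without the most abundant member for the sarcomere, calcium handling, fatty acid oxidation, cardiac transcription factor and immediate early lists, and 0.945 for long non-coding RNA genes. Calcium handling without Atp2a2, fatty acid oxidation without Fabp3 and the erythroid list passed in the new direction. The atrial, ventricular and adipocyte lists kept their call throughout, whereas the mitochondrially encoded list lost it without mt-Cytb (0.960), as the ion channel, citric acid cycle, fibroblast, macrophage, lymphocyte and alternatively spliced lists did without their member of lowest p. The adipocyte ratio ran from 0.413 to 0.459 and the atrial ratio from 1.21 to 1.31.

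On annotated models only, the mitochondrial share was 0.768% and the sarcomere share 6.9996%, and with all reads as the denominator the sarcomere share was 7.32%. Paralog shares on annotated models were 99.7% for Myh6, 93.0% for Myl2, 95.8% for Myl3, 84.6% for Actc1, 53.8% for Ldhb, 93.2% for Cox6a2, 42.7% for Cox7a1 and 96.3% for Cpt1b. The cause of these shifts was not tested.

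Genes with more than 1 major isoform numbered 276 at a minimum share of 10% and 87 at 30%, 380 with at least 20 reads and 87 with at least 100, and 270 on all spliced models. Isoform use differed in 7 genes on all models and in 24 with single-exon models kept apart by class, where a change of class between the libraries counts as a change of use. Among models with at least 5 reads, annotated ones held 80.6% of reads, ISM 8.02%, NIC 3.62%, NNC 1.37%, genomic 4.37%, antisense 1.83% and intergenic 0.214%. Shared unannotated spliced models rose, by construction, to 74.5% with at least 2 reads, 97.6% with at least 5 and 100% with at least 10, and were 28.6% of the models of replicate 1. Depth limited these results, as 61.2% and 62.7% of models had 1 read.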

Other observations

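Some reads of well-known genes lay on processed pseudogenes. Gapdh had 9 and 6 reads, whereas 18 of its 92 near-identical copies together had 1230 and 1050, led by Gm12671 (4:91851668-91852669; 472 and 402 reads, 100% identical) and Gm12033 (266 and 232 reads). Gm15459 had 1658 and 991 reads beside 1597 and 1075 on its parent Hspa8, Gm12338 had 722 and 490 beside 1538 and 1026 on Cox7c, and Mpc1-ps had 421 and 350 beside 403 and 349 on Mpc1. The levels of these genes and copies are uncertain.

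Several abundant heart genes had many reads on single-exon models within the gene. Genomic models held 75.7% and 70.7% of the reads of Pln and 53.3% and 49.4% of those of Mb, whose main one was 331 bases long (1976 and 1446 reads). In Uqcrq, a subunit of respiratory complex III, a 198-base model held 51.8% and 53.2%.

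The length trend between the libraries was weighed against 2 technical explanations, with both tests written before their results were known and the read-weighted slope chosen after the result was seen. Over 25 ERCC spike-ins the slope of the log2 ratio on log2 length was 0.611 (0.245 to 0.862), against 0.154 (0.118 to 0.190) over 2793 genes of the same lengths. The spike-in slope was positive but steeper than that of the genes, so neither stated outcome was met and a cause in library making or sequencing may hold in part. Weighted by reads, the slopes were 0.292 and 0.126. Thinning the gene counts of replicate 1 at random left the slope at 1.03 times its value (0.855 to 1.21). This excluded only an effect of read number on ratios taken from the finished counts. Such thinning keeps each gene's expected share, so it cannot show effects of depth on model building or read assignment, which stay open.

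The 30 called genes were weighed next, with the tests written before their results were known and the look at pairs of genes and at genes not called chosen after. Adding overlapping genes on the same strand brought 36.7% of them (11 genes) under 2-fold, between both stated outcomes, and an abundant neighbour with little difference lowers any fold (Podn, 76 and 26 reads, with Scp2, 366 and 374), so this stays open. Such overlaps were rarer among genes not called (6.26%; odds ratio 8.68, exact p = 1.12e-06, Fisher's exact test). Of the 11, 6 formed 3 pairs called in opposite directions, Usp50 with Gm10774, Gm45837 with Pde2a and Gm28035 with Phyhd1. Reads of 1 locus given to different genes would leave such pairs. The test takes genes as independent, which the genes of a pair are not, so its p-value and odds ratio overstate the evidence. Near-identical copies brought 10% under 2-fold, with an interval of 3.46 to 25.6 that spans the stated bound of 20%, so they stay open too. Removing the length trend left 0.667 of the calls, but all 10 lost calls ended by p and 0 by fold, with a median absolute log2 ratio of 1.52 before and 1.44 after, so the lost calls are no evidence that the trend made them, and a difference between animals was not tested.

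Antisense reads were weighed with 1 test, written before its result was known for reads opposite single-exon stretches of annotated genes. It was run instead on the reads of all antisense genes per 100 reads of annotated genes. On spike-ins 0.745 antisense reads were found per 100 sense reads (0.851 in replicate 1 and 0.639 in replicate 2), against 3.50 over annotated genes. Strand error at the spike-in rate therefore did not account for all antisense reads over genes. A rate of strand error shared by spike-ins and genes could still hold beside other sources of antisense reads, which were not tested.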
